A study of Mus musculus with 6 samples.

How the data were processed

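Total RNA of 6 mouse lungs, 3 wild-type and 3 Nogo-A/B knockout, was amplified, labelled with Cy3 and hybridised to Agilent 014868 mouse arrays, per the labels' protocols. The scanner files were made with Agilent Feature Extraction 9.5.1.1 per the file headers, while the submitters' processing notes name version 9.1. The deposited scanner files hold an intensity for every spot, a processed signal that Feature Extraction had background-subtracted and spatially and multiplicatively detrended, with low values replaced by a surrogate, per the file headers, and that was not scaled between arrays. The authors' series matrix holds log2 intensities with medians between 8.087 and 8.090 in all 6 columns. Its values followed the scanner's median spot signal without background subtraction (Spearman correlation from 0.99996 to 0.99998, across probes, which are not independent replicates), and all its 41174 rows matched a probe name. The log base and the scaling of that table were read from its values, and what the authors did to make it is not given in the sources used here. Probe positions are those of the array files, on the mouse build mm7.

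Each array held 43379 spots that were not controls, for 41174 probes. Spots flagged as outliers were left out, spots of a probe were averaged, and 30 probes flagged on an array were dropped. The main values were log2 of the processed signal minus the 75th percentile of each array. A gene was represented by the probe with the highest mean over the 6 arrays, among probes well above background on at least 3 of the 6 arrays whatever their group, which left 20244 genes. Genes were named from the array's accessions or symbols through a table of RefSeq genes (GRCm38), which matched 32734 probes. The other 8440 kept the name in the array files. The 75th percentile signal lay between 1146 and 2481, and between 48 and 99 spots were flagged per array. Probes that were not well above background on any array of a group have only a bound in that group. Their fold is given as the bright group's mean over the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own.

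Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over all genes tested, without covariates). Gene lists were tested with camera at a preset correlation of 0.01 over lists with at least 5 measured genes, adjusted over the lists, and again with the correlation estimated per list. The list tests by fry ask whether a list's genes move one way or in either direction, without comparing them with other genes. The fits with slide as a random block and with the trended, robust variance used the camera test on preranked statistics. The tests, the 42 lists and the rule for named genes were fixed before the data were examined. The rule named Rtn4 and Bpifa1, then up to 15 genes a direction past the adjusted threshold with groups that did not overlap, and, where fewer than 10 qualified, the 10 with the largest fold at an unadjusted p under 0.01 with groups that did not overlap, said not to pass the adjusted threshold. It also named up to 4 members of a list, those with the smallest p, and skipped transcripts without a gene symbol. Bpifa1 was chosen in advance from knowledge of the study. Figures were drawn with matplotlib 3.10.9.

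On simulated data with the real means and spreads of 20244 genes in this comparison, of which 200 were changed, the test recovered 20% of genes changed by 1 on the log2 scale, 68% by 2, 84% by 4 and 98% by 8. It made 11 false calls among 146, and 0 calls with nothing changed, where 129 genes reached an unadjusted p under 0.01 and 2-fold. The simulated arrays were independent and had no scan days, while the spreads they used held the differences between days. With 200 genes changed at once, the adjustment over all genes was milder than where few genes change. The recovery can therefore overstate what the test finds if few genes differ. In the real data Bpifa1, at a log2 difference of -9.81, missed the adjusted threshold. A list shifted by 1 passed the list test, and 0 of the other lists did. The simulated genes were independent of each other, while the estimated correlation within a real list reached 0.958, for mesothelial cells. The simulation therefore does not give the rate of false list calls in the real data.

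Slide and scan day were read from the files. Slide 1 held wild type 13 and knockout 1, slide 2 held knockout 11, and slide 3 held the 3 arrays of scan day 2. Values with scan day as a block and within each day are given beside Rtn4, Bpifa1, the other genes named by fold and the lists past the threshold, and not beside single list members. Within a day 1 group has a single array, which is assumed to vary like the others. Alternatives covered quantile normalization, normexp background correction with an offset of 50 followed by quantile normalization, median scaling, the authors' values, 2 other filters on dim probes, a trended robust variance, array weights, slide and replicate number as blocks, each array left out, the mean of a gene's probes, probes tested singly, an estimated correlation and fry. Scan day as a block, each scan day alone, and the fit without knockout 1 with scan day as a block were chosen after seeing the data. The lists of liver and of platelet transcripts were drawn up once the genes with the smallest p were known.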

Results

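Gene expression was measured in whole lungs of untreated male mice aged 8 weeks, 3 wild-type and 3 carrying a deletion of Nogo-A and Nogo-B, the long products of the reticulon gene Rtn4. Each lung RNA was hybridised in 1 colour (Cy3) to its own 60-mer oligonucleotide array, and the design describes the 3 lungs of a group as individual biological replicates, named by their numbers 11, 12 and 13 in the wild type and 1, 11 and 12 in the knockout. Signals are given as log2 values relative to the 75th percentile of each array. Between 68.9% and 78.0% of the 41174 probes were well above background on an array, and 20244 genes were measured well enough to be compared. The number of arrays limits the precision of every value below. The Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty were well above background on all 6 arrays. The arrays were scanned on 2 days, with wild type 13, knockout 1 and knockout 11 on day 1 and wild type 11, wild type 12 and knockout 12 on day 2. Both days held both genotypes.

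The first question was whether the targeted gene was altered in the lungs labelled knockout. A probe in the Rtn4 locus for the transcript AK047982 (mm7 chromosome 11, 29649392 to 29649451) had a signal of -2.82 ± 0.41 (SD, n = 3) in the wild type and -8.34 ± 0.21 (SD, n = 3) in the knockout, where it was not well above background on any array. Its signal was at least 14.2-fold lower in the knockout. The transcript AK080804, whose probe (29664271 to 29664330) lies between the Rtn4 probes on the same chromosome, was chosen after its values were seen because it had the smallest p of all genes. Its fitted difference with scan day as a block was -4.82, and it was -4.59 within day 1 and -5.05 within day 2. The transcript lay at background in the knockout, so these values are no measured folds. It had a signal of -3.74 ± 0.50 (SD, n = 3) in the wild type and -8.75 ± 0.31 (SD, n = 3) in the knockout, again not well above background on any knockout array. Its signal was at least 7.50-fold lower, with an adjusted p of 0.0568 in limma. Neither probe was well above background in any of the 3 lungs labelled knockout, and both were in all 3 wild-type lungs.

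The brightest Rtn4 probe (29693516 to 29693723) is assigned in the array files to 4 transcript variants of Rtn4, so it does not single out Nogo-A or Nogo-B and does not check the deletion. It measured 1.80 ± 0.42 (SD, n = 3) in the wild type and -0.55 ± 1.46 (SD, n = 3) in the knockout. The log2 difference was -2.35 (SE 0.72), at an unadjusted p of 0.0164 and an adjusted p of 0.9998. The knockout arrays were spread widely, at 1.01 for knockout 1, -0.78 for knockout 11 and -1.87 for knockout 12, while the lowest wild-type value was 1.53. With scan day as a block the difference was -2.80 (SE 0.57), and it was -2.16 within day 1 and -3.43 within day 2. A neighbouring probe (29693536 to 29694301) gave a difference of -2.28 (SE 0.75). The remaining Rtn4 probe (29658879 to 29658938) was well above background only on the array of wild type 13, so no fold was drawn from it. Among the 23 measured genes of reticulons, Nogo receptors and their partners, 2 were lower at an unadjusted p under 0.05, Rtn4 itself and Omg, a myelin ligand of the Nogo receptor, with a log2 difference of -0.81 (SE 0.27). No member passed when adjusted over the list alone or over all genes.

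**Figure D1:**
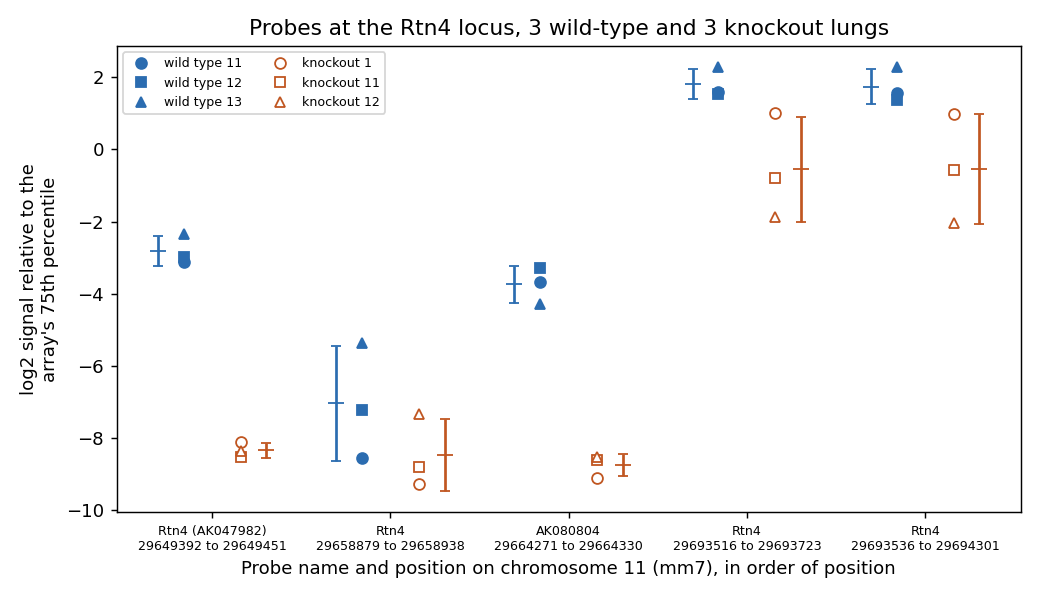
Signals of 5 probes at the Rtn4 locus on the y axis (log2 relative to each array's 75th percentile), with probes on the x axis in order of their mm7 position on chromosome 11. Points are single lungs, filled for the 3 wild-type and open for the 3 knockout lungs, and bars are mean ± SD. The knockout lungs lie near -8.34 and -8.75 at the AK047982 and AK080804 probes, while knockout 1 lies at 1.01 at the brightest Rtn4 probe.

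The second question was which other genes differed between knockout and wild-type lungs. The widest difference was in Bpifa1, also called Plunc, which encodes a protein secreted by the epithelium of the upper and conducting airways. Bpifa1 (mm7 chromosome 2, probe 153888533 to 153888953) had a signal of 3.54 ± 0.38 (SD, n = 3) in the wild type and -6.27 ± 1.42 (SD, n = 3) in the knockout, where 2 of 3 arrays were well above background. The log2 difference was -9.81 (SE 0.70), with the value of knockout 1 below the lowest detected signal of its array, at an unadjusted p of 6.62e-06 and an adjusted p of 0.0670 in limma. It was -9.70 (SE 0.79) with scan day as a block, -10.12 within day 1 and -9.28 within day 2. Bpifa1 therefore missed the adjusted threshold of 0.05 in the planned test, and it passed with adjusted p of 6.10e-04 under normexp background correction and 6.77e-04 on the authors' own processed values, in a range of 6.10e-04 to 0.980 over all alternatives. Without knockout 1 the Bpifa1 difference was -9.01 with an adjusted p of 0.0206. Over the 8 measured members of the PLUNC and BPI-fold list, Bpifa1 and Bpifb1 passed when adjusted over the list alone, and 0 passed over all genes. Bpifb1, a neighbour of the same family (chromosome 2, 153958063 to 153959091), had a signal of 1.42 ± 0.55 (SD, n = 3) in the wild type and -2.77 ± 2.23 (SD, n = 3) in the knockout, a log2 difference of -4.19 (SE 1.08), which was -3.99 with scan day as a block, -4.92 within day 1 and -3.06 within day 2. The other 6 members did not reach an unadjusted p under 0.05, and the median of the list was 0.07 against a mean of -1.64.

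Further genes with lower signals in the knockout were chosen by their fitted difference, which is no measured fold where a group lay at background. Tff2, a trefoil peptide of mucus-secreting cells, differed by -3.70 (SE 0.78), from -0.87 ± 0.82 (SD, n = 3) in the wild type to -4.56 ± 1.44 (SD, n = 3) in the knockout. Slc5a8, an epithelial transporter of monocarboxylates, was at least 7.22-fold lower in the knockout, with an adjusted p of 0.9998. Akr1c18, an aldo-keto reductase that inactivates progesterone, and Olfm4, a secreted olfactomedin, were at least 2.08-fold and 1.95-fold lower, both with an adjusted p of 0.9998. These 3 genes were not well above background on any knockout array. Cldn22, a claudin, differed by -2.84 (SE 0.38) and was well above background on 1 of 3 knockout arrays. The cytochromes P450 Cyp4a12a, Cyp2a4 and Cyp2a5 differed by -2.54 (SE 0.24), -2.39 (SE 0.53) and -2.38 (SE 0.53). Cyp2a4 and Cyp2a5 have near-identical sequences, so their probes cannot be taken as separate evidence, and the same holds for Cyp4a12a and its close copies. The difference within day 1 and within day 2 was -4.78 and -2.84 for Tff2, -3.94 and -2.57 for Slc5a8, -2.08 and -3.44 for Akr1c18, -2.62 and -3.48 for Cldn22 and -2.53 and -2.51 for Olfm4. It was -2.58 and -2.61 for Cyp4a12a, but -3.44 and -1.27 for Cyp2a4 and -3.28 and -1.32 for Cyp2a5. With the block, these 8 genes differed by -3.81, -3.25, -2.76, -3.05, -2.52, -2.60, -2.36 and -2.30 in the same order. Each of these genes reached an unadjusted p under 0.01 with groups that did not overlap, and none passed the adjusted threshold.

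Fewer genes were higher in the knockout, and by smaller amounts. Tal2, a basic helix-loop-helix transcription factor, differed by 0.91 (SE 0.19) and was well above background on 1 of 3 wild-type arrays and on all 3 knockout arrays. Selenov, a selenoprotein, differed by 0.90 (SE 0.23), Rasl10a, a Ras-like GTPase, by 0.85 (SE 0.20), Taf15, an RNA-binding protein, by 0.79 (SE 0.21), and Apol7c, an apolipoprotein L, by 0.70 (SE 0.19). The differences of Tal2, Selenov, Rasl10a, Taf15 and Apol7c with scan day as a block were 0.88, 1.02, 0.79, 0.70 and 0.67. Within day 1 they differed by 0.71, 0.90, 1.04, 0.96 and 0.53, and within day 2 by 1.05, 1.14, 0.54, 0.44 and 0.82. Of the 9 genes that were higher at an unadjusted p under 0.01 with groups that did not overlap, 3 were described on the array as similar to an immunoglobulin kappa chain variable region. None of the 9 passed the adjusted threshold.

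**Figure D2:**
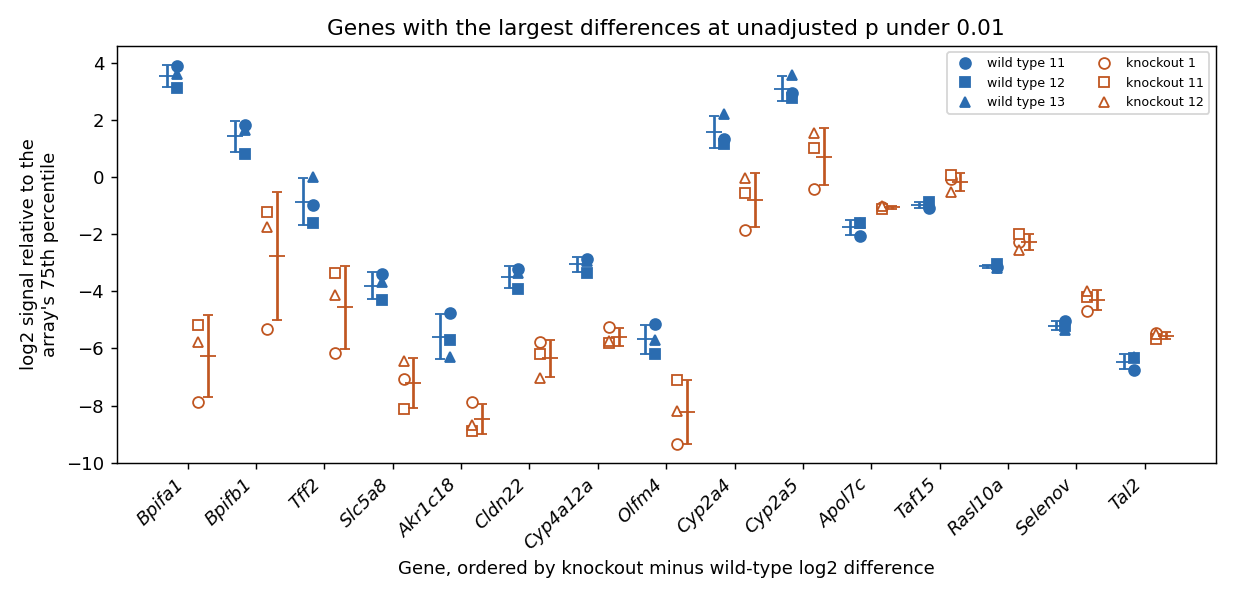
Signals of the 15 named genes on the y axis (log2 relative to each array's 75th percentile), with genes on the x axis ordered by the knockout minus wild-type difference. Points are single lungs, filled for the 3 wild-type and open for the 3 knockout lungs, and bars are mean ± SD. The genes run from Bpifa1, with a difference of -9.81, to Tal2, with 0.91.

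In total, 0 of 20244 genes passed an adjusted p of 0.05 in limma, and 194 reached an unadjusted p under 0.05, where 1012 would be expected by chance. At an unadjusted p under 0.01 and a change of at least 2-fold there were 23 genes, 22 lower and 1 higher in the knockout, where data simulated without scan days and with nothing changed gave 129. That balance differed under other settings, with 89 lower and 285 higher under array weights, 75 lower and 91 higher without wild type 13, and 27 lower and 14 higher without a filter on dim probes. The groups did not overlap for 854 genes, or 4.22%, where chance gives 10% for exchangeable arrays. Each group mixed both scan days, so differences between days lay within the groups and can lower these 3 counts below their chance values. The strongest structure in the data followed the scan day, since 3252 genes passed an adjusted p of 0.05 between the 2 days, or 2129 with genotype in the model. Arrays of the same day correlated at 0.972 to 0.994 against 0.951 to 0.966 across days. The arrays of day 2 were also those of slide 3, so the scan day cannot be told apart from the slide or from other differences between these arrays. With scan day as a block the counts were 0 and 28, and with slide as a block they were 0 and 80. Leaving out wild type 13 raised the looser count to 166, and fitting day 1 or day 2 alone raised it to 92 or 527.

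The third question was whether groups of genes differed together, tested on 42 lists of pathways and cell type markers, of which 41 had enough measured genes. Markers of neutrophils were lower in the knockout. Of 20 measured neutrophil genes 19 were lower, with a median log2 difference of -1.08, among them the granule protein Ltf at -0.86 (SE 0.24), the gelatinase Mmp9 at -1.76 (SE 0.69) and the surface antigen Cd177 at -1.12 (SE 0.44), 3 of them at an unadjusted p under 0.05 and 0 after adjustment over the list alone. The adjusted p of the list was 1.18e-15 in camera with a preset correlation, and 0.451 with an estimated correlation. The list median was -0.999 with scan day as a block, -0.06 within day 1 and -2.19 within day 2. Acute inflammatory mediators were lower for 21 of 25 members with a median of -0.40, including the cytokine gene Il1b at -2.02 (SE 0.93) and Lcn2 at -0.51 (SE 0.24), with 0 members at an unadjusted p under 0.05. Their list had an adjusted p of 1.87e-05 with a preset and 0.738 with an estimated correlation, and medians of -0.40 with the block, -0.12 within day 1 and -0.33 within day 2. Immediate early genes were lower for 17 of 23 members with a median of -0.14, including Fos at -1.33 (SE 0.57) and Egr1 at -0.80 (SE 0.32), at adjusted p of 9.57e-04 and 0.738. Their median was -0.14 with the block, 0.20 within day 1 and -0.43 within day 2. The call of the acute inflammatory list was lost without knockout 1 (adjusted p of 0.365), and that of the immediate early list without wild type 11 (0.464) or knockout 12 (0.685). The neutrophil list passed with each array left out, but those fits kept the preset correlation of 0.01. The estimate for this list was 0.40, so these passes do not show that the difference holds across mice. Its array medians overlapped between the groups, at 0.22 in knockout 11 and -0.21 in wild type 13. On day 1 alone the immediate early list passed in the higher direction (0.00910), and the neutrophil list did not pass (0.874). Under array weights the immediate early call was lost (0.115).

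Genes of MHC class II antigen presentation and of T and B cells were slightly higher in the knockout, while the natural killer cell list, with a median of 0.04 and an adjusted p of 0.652, did not pass. In the MHC class II list 10 of 11 genes were higher, with a median of 0.44, led by H2-Ab1 at 0.53 (SE 0.20) and H2-Eb1 at 0.47 (SE 0.19), whose products present peptides to CD4 T cells. The list had an adjusted p of 1.48e-07 with a preset and 0.451 with an estimated correlation, and its median was 0.42 with scan day as a block, 0.33 within day 1 and 0.59 within day 2. T cell markers were higher for 16 of 18 genes with a median of 0.25, including the T cell receptor subunits Cd3d at 0.50 (SE 0.19) and Cd3g at 0.42 (SE 0.20), at adjusted p of 1.68e-04 and 0.686. B cell markers were higher for 16 of 17 genes with a median of 0.36, including the B cell coactivator Pou2af1 at 0.47 (SE 0.25), at adjusted p of 8.04e-06 and 0.738. With the block, the medians were 0.23 for T cells and 0.27 for B cells, and they were positive within both days, at 0.29 and 0.14 for T cells and at 0.10 and 0.42 for B cells. The dendritic cell list was higher by a median of 0.22, at adjusted p of 0.0360 and 0.738, with 0.21 under the block, -0.04 within day 1 and 0.59 within day 2. In these 4 lists 0 members passed after adjustment over the list alone. With the preset correlation kept, the MHC class II list passed with each array left out. The T cell list was lost without wild type 13 (adjusted p of 0.0589) or knockout 1 (0.0674), and the B cell list without knockout 1 (0.0565). The dendritic cell list was lost without wild type 11, wild type 12, knockout 11 or knockout 12 (0.129, 0.0998, 0.114 and 0.680). Under array weights the T cell and dendritic cell calls were lost (0.109 and 0.214).

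Among airway cells, the goblet cell list was lower for 9 of 10 genes with a median of -0.47, at adjusted p of 5.95e-05 with a preset and 0.540 with an estimated correlation. Its members included Tff2, the only one to pass when adjusted over the list alone, the mucin folding factor Agr2 at -0.75 (SE 0.30) and the mucin Muc5b at -1.60 (SE 0.94). Its median was -0.28 with scan day as a block, -0.76 within day 1 and -0.07 within day 2. The basal cell list was lower for 7 of 10 genes with a median of -0.19, including the keratins Krt15 at -1.44 (SE 0.43) and Krt5 at -0.96 (SE 0.51), at adjusted p of 0.0116 and 0.738, with -0.11 under the block, where its call was lost (adjusted p of 0.162), -0.35 within day 1 and 0.09 within day 2. The PLUNC and BPI-fold list had an adjusted p of 0.0360 and 0.686 in the lower direction, with Bpifa1 and Bpifb1 far below the median of 0.07. With the block its median was 0.07 and its call was lost (0.162), and the medians were -0.29 within day 1 and 0.27 within day 2, where its adjusted p was 0.990. The goblet list was lost without wild type 13 (adjusted p of 0.138), the basal list without wild type 11, wild type 13 or knockout 11 (0.0741, 0.0966 and 0.658), and the PLUNC list without wild type 13, knockout 11 or knockout 12 (0.531, 0.0858 and 0.0770). Under array weights all 3 of these calls were lost (0.115, 0.214 and 0.369). The club cell list was not past the threshold (adjusted p of 0.303) with a median of 0.22 and a mean of -0.28, since the antimicrobial lectin Reg3g at -5.69 (SE 1.87) and the secretoglobin Scgb3a1 at -2.86 (SE 1.19) lay apart from the rest, such as the club cell cytochrome Cyp2f2 at 0.39 (SE 0.20). Reg3g was well above background on 2 of 3 knockout arrays. The knockout lungs varied widely, at -3.74 ± 3.99 (SD, n = 3) for Reg3g and 2.08 ± 2.51 (SD, n = 3) for Scgb3a1. The SDs of the wild type were 0.45 and 0.37. The ciliated cell list had a median of 0.084 over 29 genes, -0.41 within day 1 and 0.57 within day 2, and an adjusted p of 0.183. Alveolar type 2 cells, including the surfactant gene Sftpc at 0.45 (SE 0.21), had a median of 0.06 and an adjusted p of 0.303. The alveolar type 2 list passed with scan day as a block, with a median of 0.15 and an adjusted p of 2.90e-04 (0.523 with an estimated correlation), and its medians were 0.19 within day 1 and 0.21 within day 2.

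Markers of tissues around the lung also differed between arrays. Skeletal muscle genes were higher on the array of knockout 1, with a list median of 6.79 above the gene means, against values between -2.92 and 0.48 on the other 5 arrays. As a list they were higher for 17 of 17 genes with a median of 2.23, at adjusted p of 0.00101 with a preset and 0.806 with an estimated correlation, and the median was 1.58 with scan day as a block, where the call was lost (adjusted p of 0.382), 4.30 within day 1 and -1.90 within day 2, where the list passed in the lower direction (8.37e-06). The parvalbumin gene Pvalb, at 3.58 (SE 2.89), the nebulin gene Neb, at 3.01 (SE 2.51), and the fast-fibre gene Actn3, at 2.73 (SE 2.36), turned to -1.40, -0.95 and -0.64 on day 2 alone. Pvalb was well above background on 4 of 6 arrays and Neb on 3 of 6. Neb lay below the lowest detected signal on every day 2 array, so its day 2 value is no measured difference. Without knockout 1 the list turned to the lower direction (adjusted p of 0.0727), and without wild type 13 its call was lost (0.170). Adipocyte genes were lower for 12 of 12 genes with a median of -0.71, including the adipokines Adipoq at -2.70 (SE 0.96) and Cfd at -2.75 (SE 0.998) and the gluconeogenic enzyme Pck1 at -3.09 (SE 0.99), at adjusted p of 2.84e-09 and 0.451. Their median was -1.46 with scan day as a block, -1.25 within day 1 and -1.18 within day 2. With the preset correlation kept, the adipocyte list passed with each array left out but not with array weights (adjusted p of 0.239). Cardiomyocyte genes had a median of -0.01 and an adjusted p of 0.833. Their list passed in the lower direction with scan day as a block, with a median of -1.02 and an adjusted p of 4.88e-12 (0.523 with an estimated correlation), and medians of -0.90 within day 1 and -1.38 within day 2. Smooth muscle (median 0.33), mesothelial (-0.45), eosinophil and mast cell (-0.14) and strain-variable (-0.06) genes passed with the preset correlation at adjusted p of 0.0119, 0.0249, 0.0360 and 0.0223, and had adjusted p of 0.806, 0.841, 0.738 and 0.451 with an estimated correlation. The medians of these 4 lists were 0.07, 0.14, 0.00 and -0.15 with the block, were 0.20, 0.01, -0.18 and -0.05 within day 1, and were -0.25, 0.27, 0.05 and -0.16 within day 2. With the block all 4 calls were lost, at adjusted p of 0.471, 0.240, 0.471 and 0.162. On day 2 alone the smooth muscle list passed in the lower direction (0.00228). In the strain-variable list, genes known to differ between mouse strains, 10 of 15 genes were lower and 5 higher. Wdfy1 differed by -0.83 (SE 0.18) and Ide by -0.68 (SE 0.24). The groups of both genes did not overlap, and both had an adjusted p of 0.9998 in limma. Each of these 4 lists was lost when any of 4 arrays was left out.

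The asthma-related list of type 2 inflammation had a median of -0.08 and a mean of 0.01 over 22 genes, with 0 members at an unadjusted p under 0.05 and an adjusted p of 0.673. The interferon-stimulated list had a median of -0.06 and an adjusted p of 0.662, with the chemokine gene Cxcl9 at 0.47 (SE 0.16). The 25 lists that did not pass without a block had medians between -0.17, for neurons and Schwann cells, and 0.22, for club cells. They included extracellular matrix, endoplasmic reticulum stress, circadian clock, glucocorticoid response, proliferation, cholesterol synthesis, xenobiotic response, alveolar type 1, endothelial, erythroid, plasma, natural killer, macrophage, fibroblast, chondrocyte, thyroid and thymocyte genes. Of 41 lists, 16 passed with the preset correlation, 6 higher and 10 lower, and 0 passed with an estimated correlation. With scan day as a block 12 passed, among them the cardiomyocyte, alveolar type 2 and proliferation lists, the last with a median of 0.11 and an adjusted p of 0.00490 (0.845 with an estimated correlation).

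**Figure D3:**
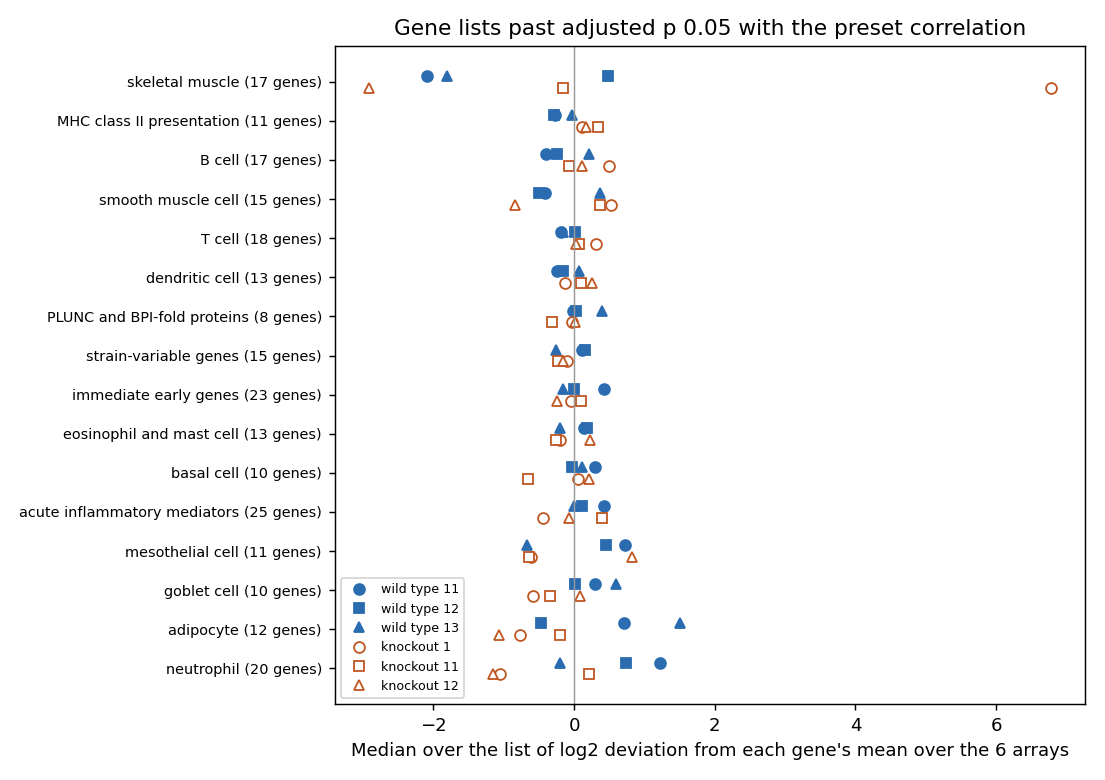
The 16 gene lists past an adjusted p of 0.05 with the preset correlation on the y axis, and on the x axis the list median of each array's log2 deviation from the genes' means over the 6 arrays. Points are single lungs, filled for the 3 wild-type and open for the 3 knockout lungs. Knockout 1 lies at 6.79 for skeletal muscle, and the 3 MHC class II values of the knockout lie above those of the wild type.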

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

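Each of the 23 genes past an unadjusted p of 0.01 and 2-fold kept its sign under every alternative that measured it, and so did Rtn4 and Bpifa1. In the main values the groups of all these genes did not overlap. Leaving out arrays, fitting a single day, blocking or weighting arrays could therefore not turn their sign, so those settings were no test of it. Of 1879 values of 90 other transcripts under the alternatives, namely the genes named by fold, AK080804 and the up to 4 members with the smallest p of the 16 lists past the threshold and of the Nogo, club cell, alveolar type 2 and interferon lists, 41 had the opposite sign. The sign turned on day 1 alone for Pirb (0.34), Pltp (-0.30), Lbp (-0.28), Cd244a (0.55) and Hdc (0.48). With the replicate block it turned for Rtn2 (-0.085), Pvalb (-0.94) and Actn3 (-0.66). Without knockout 1 it turned for Rtn2 (-0.13) and Atp2a1 (-0.098), which ranged up to 0.99 and 1.99 with another array left out. On day 2 alone it turned for Rtn2 (-0.24), Psmb9 (-0.052), Iigp1 (-0.037), Bst2 (-0.057), Krt13 (0.18), Krt14 (0.010), Tpm2 (-0.25), Pvalb (-1.40), Neb (-0.95), Actn3 (-0.64), Atp2a1 (-0.17), Wt1 (0.036), Lrrn4 (0.42) and Muc16 (0.85). Without knockout 1 with scan day as a block it turned for Rtn2 (-0.16), Tpm2 (-0.017), Des (-0.011), Neb (-0.23), Atp2a1 (-0.22), Lrrn4 (0.0052) and Muc16 (0.24). On the authors' values it turned for Cbr2 (-0.0063), Sftpa1 (-0.050) and Lyz1 (-0.0052). With slide as a fixed block it turned for Krt14 (0.017), Wt1 (0.049), Lrrn4 (0.037) and Muc16 (0.15). With normexp it turned for Sftpa1 (-0.016) and Lyz1 (-0.0024). With scan day as a block it turned for Muc16 (0.089). Of these 90 transcripts, AK080804 alone passed the adjusted threshold under an alternative. Rtn4 stayed between -1.69 and -3.43 and past no adjusted threshold. The count of genes past an adjusted p of 0.05 was 0 and became 1 with normexp, the authors' values or the trended robust variance and 2 with median scaling, array weights, slide as a random block or probes tested singly. Leaving out each array gave 0 to 1, with 1 only without knockout 1. Those genes were Bpifa1 and AK080804, or the probes of AK047982 and AK080804 when tested singly. Bpifa1 then measured -7.98 with normexp, -9.86 with median scaling, -8.12 on the authors' values, -9.81 with the trended robust variance, -9.66 with array weights and -10.05 with slide as a random block. It ranged from -10.37 to -9.01 with an array left out, and its adjusted p over all alternatives ran from 6.10e-04 to 0.980. The filter on all 6 arrays removed Bpifa1. The looser count of 23 became 14 with normexp, 15 on the authors' values, 41 without a filter, 374 with array weights, 80 with slide as a fixed block, 52 with slide as a random block, 15 to 166 with an array left out (15 without wild type 11, 36 without wild type 12, 166 without wild type 13), 92 on day 1 alone, 527 on day 2 alone and 42 without knockout 1 with scan day as a block. The number of lists was 16 and became 0 with an estimated correlation and 0 with fry for a shift in one direction, while fry for changes in either direction found 1, the PLUNC and BPI-fold list (adjusted p of 0.00620). Of the 16 lists, 10 lost their call under array weights, namely PLUNC, immediate early, strain-variable, goblet, basal, skeletal muscle, adipocyte, T cell, eosinophil and mast cell, and dendritic. With slide as a fixed block 8 did, namely PLUNC (0.382), strain-variable (0.350), basal (0.977), smooth muscle (0.237, direction turned to lower), skeletal muscle (0.131), eosinophil and mast cell (0.485), dendritic (0.106) and mesothelial (0.382, direction turned to higher). Quantile normalization lost 5, namely PLUNC, strain-variable, eosinophil and mast cell, dendritic and mesothelial. The calls lost were 4 without a filter, 4 with slide as a random block, 2 with normexp, the authors' values or the mean of a gene's probes, 1 with median scaling, the filter on all 6 arrays or the trended robust variance, and 4 to 7 with an array left out. Scan day as a block lost 7, day 1 alone 10, day 2 alone 8, and the fit without knockout 1 with scan day as a block 8. A list passed in the opposite direction on day 1 alone (immediate early, higher, 0.00910), on day 2 alone (smooth muscle, 0.00228, and skeletal muscle, 8.37e-06, both lower) and without knockout 1 with scan day as a block (skeletal muscle, lower, 0.0180). The cause of these shifts was not tested. The fits that left arrays out also held fewer arrays. The scan-day settings, among them the fit without knockout 1 with scan day as a block, were chosen after seeing the data.

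Replicate numbers 11 and 12 occur in both groups but the labels do not say that they pair lungs, and the deviations of same-numbered lungs correlated at -0.24 and 0.42. With the replicate block the looser count was 99, the adjusted count 0, the number of lists 15, although 6 of the 16 lost their call (T cell 0.360, acute inflammatory 0.143, goblet 0.143, PLUNC 0.229, smooth muscle 0.0574 and skeletal muscle 0.0546 as adjusted p, the last in the lower direction), Rtn4 -2.89 and Bpifa1 -8.98. Signal over background limits AK047982, AK080804, Slc5a8, Akr1c18 and Olfm4, which have only a bound in the knockout. It also limits Neb, which lay below the lowest detected signal on every day 2 array, so its turned sign on day 2 alone is no measured reversal.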

Other observations

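The tests chosen only after the result was seen are the scan-day test of the airway genes, the 3 tests of knockout 1 and the platelet and liver lists, and the intervals around the airway lists and the share near Rtn4 were also settled with those values known, as was how these intervals were read.

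Values are given for a list of platelet and megakaryocyte transcripts on which no set test was run. It was written after the values of 5 of its members had been seen, so those 5 are left out here. The genes with the smallest p were known by then, and Ppbp and Pf4 also had an unadjusted p under 0.01 in limma. The remaining genes are therefore no independent check. Of the 23 remaining genes 23 had lower means in the knockout, with a median log2 difference of -0.70. At an unadjusted p under 0.05 there were 10 of them, and 0 passed when adjusted over all genes. The platelet chemokines Pf4 and Ppbp differed by -0.85 (SE 0.22) and -0.81 (SE 0.20), and the integrin subunit Itga2b by -0.71 (SE 0.20). The list median deviated by 0.43, 0.29 and 0.07 in wild type 11, 12 and 13 and by -0.18, -0.14 and -0.59 in knockout 1, 11 and 12. It was -0.67 with scan day as a block, -0.20 within day 1 and -0.82 within day 2. Erythroid genes, in contrast, had a median of -0.01.

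Of 31 measured liver transcripts some varied widely between arrays of both genotypes, with a range of 9.64 for Mup1 and 3.10 for Alb, and others little, with 0.38 for Vtn, 0.48 for Itih4 and 0.55 for Trf. The median of the list deviated by 0.21, 0.70 and -0.37 in wild type 11, 12 and 13 and by 0.57, -0.52 and -0.36 in knockout 1, 11 and 12. Mup1, a major urinary protein gene, measured -0.444 in wild type 11, 1.099 in wild type 12 and -0.27 in knockout 1, against -6.27 in wild type 13, -8.55 in knockout 11 and -6.11 in knockout 12. Alb measured -2.20, -1.35, -4.00, -1.54, -4.45 and -4.02 on wild type 11, 12 and 13 and knockout 1, 11 and 12.

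The secreted airway genes Bpifa1, Bpifb1, Tff2, Reg3g and Scgb3a1, picked by their values, had lower means in the knockout by -9.81 to -2.86, while 14 of 19 club cell genes were higher and none of the 5 passed over all genes. Knockout 1 had the lowest values of Bpifa1, Bpifb1 and Tff2, at -7.88, -5.33 and -6.17, the first below its array's lowest detected signal. Knockout 11 had -5.17, -1.24 and -3.38, and knockout 12 had -5.77, -1.74 and -4.15. Chondrocyte genes did not fall to the -1 predicted for less cartilage-bearing airway as the whole cause. Their median was -0.072 over 11 genes (95% interval -0.45 to 0.30 over the arrays), -0.26 within day 1 and 0.29 within day 2. Of these genes, 5 were higher and 6 lower. They were dim, with a wild-type median 2.18 above the lowest detected signal on the log2 scale, which limits the fall that they could show. How much of their wild-type signal came from airway cartilage was not tested, so the list cannot decide on less upper airway. Less conducting airway as the whole cause is argued against by ciliated cell genes, whose median was 0.084 over 29 genes (-0.69 to 0.86). That list does not tell upper from lower airways. Both medians lie above the -0.5, and both intervals above the -1, but these limits were set in advance for the medians alone. Holding the intervals against -1 was settled with the values known, and the ciliated interval reaches below -0.5. The Bpifa1 difference was -9.70 with scan day as a block. The groups did not overlap, with the lowest wild-type value at 3.13 and the highest knockout value at -5.17. The block value and the direction within each day were thus fixed by values already seen, so the block is no further test. Both days held both genotypes, so this gap itself argues against the scan day as the whole cause for Bpifa1. Less upper airway stays open. So do an airway share as part of the pattern, with the basal keratins Krt15 and Krt5 at -1.44 and -0.96, and an effect of the deletion itself, both untested. The strain background stays open too. The strain-variable list passed in camera with the preset correlation (adjusted p of 0.0223) but not with an estimated one (0.451). Its link to the airway genes was not tested.

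The brightest Rtn4 probe kept most of its signal in knockout 1. A wild-type lung under the label knockout 1 is argued against, since the AK047982 probe was not well above background there. Its signal differed by -4.99 from the lowest wild-type array, but this is a difference to an undetected value. The lowest detected signal on the array of knockout 1 was -7.02, against -3.13 for the probe on the lowest wild-type array. The scan day is argued against by the difference of 1.80 to knockout 11, scanned on the same day. Knockout 11 was on another slide than knockout 1, and the slide as a cause was not tested. Skeletal muscle in the tissue piece, with a reticulon transcript of its own that the deletion of Nogo-A and Nogo-B leaves in place, may contribute. Its list median in knockout 1 was 6.94 above the next knockout array, but with 3 knockout arrays and no probe specific to that transcript this cannot be told apart from other sources of the same 3' sequence.

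DNA of the donor strain kept around the targeted locus could make genes near Rtn4 differ more often. Of 203 tested genes within 20 Mb, Rtn4 and AK080804 left out, 1 (Vwc2) reached an unadjusted p under 0.01, a share of 0.493% (exact binomial 95% interval 0.0125% to 2.71%). The 95th percentile of windows of as many genes elsewhere was 0.985%, and a share at or below it had been set in advance as evidence against this explanation. The interval, added once the share was known, reaches above that percentile and alone keeps the question open.

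The 6 arrays allow 10 splits into 3 and 3, so no share under 0.05 can be reached. For genes past an adjusted p of 0.05 the real value was 0 and the highest other 3252, from the split that follows the scan day, which points to that structure of the samples. All 10 splits gave at least 0. For the looser count the real value was 23 and the highest other 1807, again the scan-day split. At least as many came from 4 of the 10 splits, the real one among them. For the gene lists the real value was 16 and the highest other 18, and again 4 splits, with the real one counted, gave at least as many. With scan day as a block the 3 counts were 0, 28 and 12.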
